A study of Homo sapiens with 4 samples.

How the data were processed

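RNA was sequenced from MCF-7 cells, an established line from a human breast tumour that is known to lack caspase-3, the protease that dismantles the cell in apoptosis. Per the labels, the cells had been stably transfected with an empty vector (called deficient in the titles) or with a caspase-3 cDNA (called proficient), and each line was either left untreated or given docetaxel, a drug that stabilises microtubules. The treated cultures received 10 nM docetaxel for 24 h and then drug-free medium for 24 h. The design was thus 2 by 2, with 4 libraries and 1 library per group. No group had a replicate, so no comparison between single libraries has a replicate check or a p-value. Per the labels, the RNA was depleted of ribosomal RNA, while the extraction protocol also names purification of mRNA as an option; which was used for each library is not stated beyond the description. The library kit carries no statement on strand, so reads of genes that overlap on opposite strands cannot be separated here.

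The authors aligned the reads with TopHat and quantified transcripts with Cufflinks on hg19, per the submitters' processing notes, which give no version for either. Each of the 4 files was a Cufflinks table of 210321 Ensembl transcripts from 61784 genes. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, with a 95% interval per transcript. The deposited coverage column is a signal, the mean read depth per base of each transcript, and is not scaled between libraries. Coverage times length, summed over transcripts, gave 520, 483, 409 and 478 megabases of read sequence in the empty-vector untreated, empty-vector docetaxel, caspase-3 untreated and caspase-3 docetaxel libraries. With the read bases per fragment that the intervals imply, this came to 3.50, 3.32, 2.81 and 3.29 M fragments. These are estimates, since the files hold no counts. The deposited intervals had a median half-width of 60.5% to 64.8% of the value at 1 to 2 FPKM, 27.9% to 32.4% at 5 to 10 FPKM and 12.6% to 15.1% at 50 to 100 FPKM, depending on the library. They cover the error of the estimate in 1 library, not the spread between cultures, and reads without molecular identifiers are not independent molecules. In 1.58% to 1.80% of the transcripts above 0, the interval did not contain the FPKM itself. In the empty-vector untreated library, those with an FPKM above their interval had a median length of 455 nt.

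A gene's value was the sum of the FPKM of its transcripts. Genes were kept when their mean over the 4 libraries was at least 1 FPKM and their longest transcript was at least 300 nt, which left 13472 genes. Genes with very short transcripts alone were left out because transcripts under 300 nt carried 18.3% to 35.9% of the summed FPKM on 1.26% to 2.24% of the read bases. Transcripts under 300 nt that belong to kept genes stayed in the sums. Ratios were taken as log2((FPKM + 1)/(FPKM + 1)), where 0 is no difference and 1 is 2-fold. Each ratio has an interval of 2 standard errors to either side, computed from the deposited intervals. A gene counted as higher or lower when it was at least 2-fold apart by this measure, which is a rule of size and not a test. The 4 comparisons were docetaxel against untreated in each line, and caspase-3 against empty-vector cells under each treatment. The difference of responses is the log2 ratio of docetaxel against untreated in caspase-3 cells minus that in empty-vector cells.

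For docetaxel averaged over both lines and caspase-3 averaged over both treatments, limma 3.58.1 in R 4.3.3 fitted an additive model on log2(FPKM + 1) with a mean-variance trend, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. It sets 2 libraries against 2 with 1 residual degree of freedom, and its residual holds the difference between the 2 responses as well as noise. The 2 libraries of a line are not replicate transfections, so a result for caspase-3 is a difference between the lines, whatever its cause. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

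Lists of genes were fixed before the data were examined, as were the named-gene rule, the comparisons and every alternative except the 3 given as added. There were 25 lists with 549 genes, of which 548 were matched to the files. They covered p53 targets, mitosis, DNA replication, replication-dependent histones, apoptosis regulators, tubulins, estrogen receptor targets, luminal identity, interferon-stimulated genes, NF-kB and inflammatory secretory genes, unfolded protein and integrated stress responses, heat shock, immediate early genes, mesenchymal and stem-like genes, and drug transport and metabolism. The others were cholesterol biosynthesis, hypoxia and glycolysis, autophagy and lysosome, ribosomal proteins, mitochondrial transcripts, non-polyadenylated and nuclear RNAs, and markers of fibroblasts, blood cells, endothelium and basal mammary cells. Each list's median log2 ratio was placed among 10000 random gene lists of the same size, matched on expression in 20 bins; a median between the 2.5 and 97.5 percentiles is called within the matched range. This describes these libraries only, because list members vary together.

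Of the kept genes, 435, 398, 450 and 424 were listed at exactly 0 in the empty-vector untreated, empty-vector docetaxel, caspase-3 untreated and caspase-3 docetaxel libraries, and 1030 in at least 1 library. Such genes are named only as listed at 0, with no fold. The rule for named genes took, per comparison, the 10 highest and 10 lowest log2 ratios among genes with at least 5 FPKM in the higher library, at least a 2-fold difference and intervals that did not overlap. It took the 5 highest and 5 lowest for the difference of responses, the 5 smallest adjusted p-values per direction for the averaged comparisons, up to 4 members of each list, and CASP3. As first written, the rule gave almost only genes listed at 0 (10 of 10 in most comparisons, and never fewer than 8), so it was applied to genes above 0 in the compared libraries, a choice made after the data were seen. Of the 12442 genes above 0 in all libraries, 2897, or 23.3%, had an annotated span that overlaps another kept gene.

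The alternatives were a pseudocount of 0.1 or 5, no filter on low values, a mean of at least 5 FPKM, rescaling by the median ratio or to an equal sum, all gene lengths, each gene's highest transcript only, transcripts with status OK only, non-overlapping intervals, and limma without a trend. The 3 added after seeing the data were genes above 0 in all libraries, such genes that overlap no other kept gene, and non-overlapping intervals in genes above 0 in both libraries. The 2-fold rule and limma were also tested on simulated data with Poisson noise at the depth of the empty-vector comparison: of 100 genes set apart 2-fold, which is the threshold itself, and 100 set apart 4-fold, the rule of size found 28% and 95% and limma found 34% and 87%. Of 12242 unchanged genes, 170 passed the rule of size and 4 were called by limma. The simulation held counting noise alone, with no spread between cultures, and was built on genes above 0 in all libraries. Its unchanged genes had an SD of the log2 ratio of 0.294, against 0.501 in the measured empty-vector comparison. These rates therefore need not hold for the data. No sample or file was left out.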

Results

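RNA levels of 13472 genes were compared in MCF-7 breast cancer cells that carried either an empty vector or a caspase-3 cDNA, each untreated or exposed to docetaxel. There were 4 libraries, 1 for each of empty-vector untreated, empty-vector docetaxel, caspase-3 untreated and caspase-3 docetaxel cells. Values given as 4 numbers follow this order and are FPKM as the authors computed them on hg19. The libraries held an estimated 3.50, 3.32, 2.81 and 3.29 M fragments. No group had a replicate, so differences between single libraries have no replicate check and no p-value. The intervals given for single genes cover the error of the estimate alone. Log2 values across kept genes had a Pearson correlation of 0.940 between the empty-vector libraries and 0.928 between the caspase-3 libraries. Between the lines it was 0.885 when untreated and 0.903 after docetaxel. Transcripts of the mitochondrial genome took 7.14%, 7.39%, 8.83% and 10.0% of the read bases.

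CASP3, which encodes the transfected protease, was read first. The gene (ENSG00000164305, chromosome 4, positions 185548850 to 185570663) had 1.74 FPKM (95% interval 0.869 to 2.73) in empty-vector untreated cells and 1.66 FPKM (0.569 to 4.33) in empty-vector docetaxel cells. It had 3.62 FPKM (2.05 to 5.04) in caspase-3 untreated cells and 3.60 FPKM (2.05 to 5.14) in caspase-3 docetaxel cells. The log2 ratio of caspase-3 to empty-vector cells was 0.75 (interval 0.08 to 1.43) when untreated and 0.79 (−0.34 to 1.92) after docetaxel. These values rest on an estimated 14.1, 7.05, 23.8 and 30.0 fragments, and the FPKM intervals of the lines overlapped under each treatment. Docetaxel against untreated gave −0.04 (−1.17 to 1.09) in empty-vector cells and −0.01 (−0.68 to 0.67) in caspase-3 cells, so no difference with docetaxel was detectable at this depth. FPKM was computed over annotated transcripts of 549 to 2673 nt, and which part of them the cDNA covers is not stated in the labels. How far these values count the cDNA's own transcript is therefore not known.

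Docetaxel against untreated in empty-vector cells asks how cells without the cDNA responded to the drug. Targets of p53, the transcription factor that answers DNA damage and mitotic failure, had a median above the matched range after docetaxel: 8 of 31 measured members were at least 2-fold higher, 0 were lower and 23 were within 2-fold, with a median log2 ratio of 0.82. CDKN1A (ENSG00000124762, chromosome 6, positions 36644305 to 36655116), which encodes the cell cycle inhibitor p21, went from 86.5 to 363 FPKM (log2 2.06, interval 1.89 to 2.23). GADD45A, a growth arrest gene, went from 9.73 to 52.1 FPKM (2.31, 1.70 to 2.91), and the pro-apoptotic BBC3 from 12.2 to 39.2 FPKM. Replication-dependent histone genes, close paralogs that can share reads, had 12 of 27 at least 2-fold up, 0 down, 13 within 2-fold and 2 listed at 0 (median 1.11, above the matched range); the linker histone HIST1H1C went from 51.4 to 204 FPKM. Most histone transcripts lack a poly(A) tail, and the list of non-polyadenylated and nuclear RNAs also had a median above the matched range in this comparison (0.72); RN7SK had 25.9 and 108 FPKM.

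The medians of the cell division lists were below the matched range in the same cells, with most members within 2-fold. Of 33 mitosis and G2/M genes, 5 were at least 2-fold lower, 0 higher, 26 within 2-fold and 2 listed at 0 (median −0.64, below the matched range). TOP2A, the topoisomerase that untangles chromosomes, went from 34.2 to 11.4 FPKM (log2 −1.50, −1.74 to −1.27), and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, from 147 to 62.4 FPKM. Of 31 DNA replication and G1/S genes, 3 were lower, 0 higher, 27 within 2-fold and 1 listed at 0 (median −0.69). RRM2, a subunit of the enzyme that makes deoxynucleotides, went from 128 to 34.7 FPKM (−1.86, −2.13 to −1.58). Luminal identity genes had a median of −0.31, below the matched range, with 1 of 16 lower and 15 within 2-fold; ESR1, the estrogen receptor, went from 39.2 to 14.0 FPKM. The 19 hypoxia and glycolysis genes had a median of −0.27, with 1 lower, 17 within 2-fold and 1 listed at 0; it lay inside the matched range when only each gene's highest transcript was used.

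The inflammatory and interferon lists had medians above the matched range in docetaxel-treated empty-vector cells, with most members within 2-fold. Of 13 NF-kB and inflammatory secretory genes, 4 were at least 2-fold higher, 7 within 2-fold and 2 listed at 0 (median 0.99); the cytokine LIF went from 1.93 to 7.76 FPKM and TNFAIP2 from 8.01 to 24.1 FPKM. Of 27 interferon-stimulated genes, 8 were higher and 19 within 2-fold (median 0.47), among them OAS1, an activator of antiviral RNA decay (4.50 to 19.8 FPKM), and IFI6 (13.6 to 50.6 FPKM). Immediate early genes had a median of 0.29, with 1 of 16 higher, 1 lower and 14 within 2-fold: the AP-1 members FOSL1 and FOS went apart, from 1.43 to 15.9 and from 27.3 to 7.22 FPKM. Tubulins, the drug's target family, had a median of 0.33, with 4 of 14 higher, 9 within 2-fold and 1 listed at 0, and TUBB3 went from 304 to 658 FPKM; among genes above 0 in all libraries the median was inside the matched range. The medians of the 7 mesenchymal and stem-like genes (0.57, with 1 lower and 6 within 2-fold) and the 5 non-polyadenylated and nuclear RNAs (0.72, with 1 higher, 3 within and 1 listed at 0) were above the matched range, the former not without the filter on low values or with the highest transcript only. The mitochondrial median was −0.06, below the matched range, and 0.01 under median-ratio scaling. It was inside the range without the filter on low values, with status OK transcripts only and among genes above 0 that overlap no other. Medians were within the matched range for estrogen receptor targets (0.10), apoptosis regulators (0.08), the unfolded protein and integrated stress response (0.11), heat shock (0.02), drug transport and metabolism (−0.01), cholesterol biosynthesis (−0.21), autophagy and lysosome (0.10) and ribosomal proteins (0.19). TFF1, a classical estrogen-induced gene, nevertheless went from 3214 to 8125 FPKM.

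In empty-vector cells, 596 genes were at least 2-fold higher after docetaxel and 555 were lower, of which 213 and 185 were listed at 0 in a compared library. Among the 12442 genes above 0 in all libraries the counts were 347 and 337. The side with more genes depended on scaling: sum scaling gave 612 higher and 706 lower. Of the named extremes, FOSL1 and the cytokine IL32 (2.26 to 17.6 FPKM) were among the 10 highest, and BAALC (27.7 to 2.12 FPKM), the lipid kinase PI4K2B (32.3 to 4.15 FPKM) and the adenylate kinase AK1 (81.3 to 17.4 FPKM) among the 10 lowest. Another kept gene overlapped 6 of the 10 highest and 3 of the 10 lowest, as with XPNPEP3 (2.14 to 31.5 FPKM, overlapping RBX1). RP11-43F13.1 and AC012318.3, also among the highest, had ratios below 0 once transcripts without status OK were left out.

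Docetaxel against untreated in caspase-3 cells asks the same of cells with the cDNA. Targets of p53 had 10 of 31 at least 2-fold up, 1 down and 20 within 2-fold (median 0.74, above the matched range). CDKN1A went from 55.9 to 265 FPKM (log2 2.23, 2.03 to 2.42), GADD45A from 5.38 to 22.0 FPKM (1.85, 1.16 to 2.54), and SESN1, a stress-induced inhibitor of growth signalling, from 1.79 to 6.92 FPKM. Histone genes were higher in 7 of 27 and lower in 1, with 16 within 2-fold and 3 listed at 0 (median 0.65, inside the matched range without the filter on low values); non-polyadenylated and nuclear RNAs had a median of 0.40, within the matched range. NF-kB and inflammatory secretory genes were higher in 4 of 13, with 8 within 2-fold and 1 listed at 0 (median 0.82); LIF went from 1.27 to 4.28 FPKM. The median of the NF-kB list was inside the matched range at a mean of at least 5 FPKM and with the highest transcript only.

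The estrogen receptor, sterol and glucose lists had medians above the matched range in docetaxel-treated caspase-3 cells, with most members within 2-fold. Estrogen receptor targets had a median of 0.56, above the matched range, with 5 of 27 at least 2-fold higher, 21 within 2-fold and 1 listed at 0. GREB1, a cofactor of the estrogen receptor, went from 31.5 to 105 FPKM (log2 1.71, 1.54 to 1.87) and the insulin receptor substrate IRS1 from 8.63 to 21.9 FPKM. Cholesterol biosynthesis had a median of 0.55, with 2 of 17 higher and 15 within 2-fold. The highest member, the HMG-CoA synthase HMGCS1, went from 6.25 to 20.9 FPKM, although its highest transcript alone had a negative ratio. With the highest transcript only the list's median was inside the matched range. Hypoxia and glycolysis genes had a median of 0.34, with 2 of 19 higher, 16 within 2-fold and 1 listed at 0; SLC2A1, the glucose transporter GLUT1, went from 52.5 to 121 FPKM (1.19, 1.01 to 1.36). Immediate early genes had a median of 0.45, with 3 of 16 higher and 13 within 2-fold, such as KLF10 (12.5 to 29.8 FPKM). This median too was inside the matched range with the highest transcript only.

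Of the division lists, replication was below the matched range in these cells and mitosis was not. Mitosis and G2/M genes had a median of 0.05, within the matched range and −0.03 under median-ratio scaling, with 32 of 33 within 2-fold and 1 listed at 0; TOP2A went from 38.6 to 26.5 FPKM (log2 −0.52, −0.71 to −0.34). DNA replication and G1/S genes had a median of −0.36, below the matched range, with 1 of 31 lower, 29 within 2-fold and 1 listed at 0; the thymidine kinase TK1 went from 152 to 82.2 FPKM. Luminal identity genes had a median of −0.45, with 1 of 16 lower and 15 within 2-fold; the lower gene was ELF3, an epithelial transcription factor (111 to 25.1 FPKM). This median was inside the matched range among genes above 0 that overlap no other. Drug transport and metabolism genes had a median of −0.39, with 1 of 13 higher, 1 lower and 11 within 2-fold: CYP1B1, a cytochrome that oxidises estrogens, went from 4.68 to 22.2 FPKM and the exporter ABCC3 from 81.3 to 36.8 FPKM. That median was inside the matched range at a pseudocount of 5 and without the filter on low values. All 13 heat shock genes and all 13 mitochondrial genes were within 2-fold, with medians of 0.14 and 0.04 above the matched range. The middles of their matched lists were −0.21 and −0.26. The mitochondrial median was −0.07 under median-ratio scaling. Medians were within the matched range for apoptosis regulators (0.05, and −0.04 under median-ratio scaling), tubulins (0.12), interferon-stimulated genes (0.30), the unfolded protein and integrated stress response (0.16), mesenchymal and stem-like genes (0.59), autophagy and lysosome (0.18) and ribosomal proteins (−0.35).

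In caspase-3 cells, 834 genes were at least 2-fold higher after docetaxel and 723 were lower, of which 251 and 249 were listed at 0 in a compared library; among genes above 0 in all libraries the counts were 560 and 446. The side with more genes depended on scaling, with 709 higher and 857 lower under median-ratio scaling and 1249 and 600 under sum scaling. The highest among the named genes was NEAT1 (ENSG00000245532, chromosome 11, positions 65190245 to 65213011), the nuclear RNA on which paraspeckles form, which went from 10.7 to 118 FPKM (log2 3.35, 3.16 to 3.53). IDS, a lysosomal sulfatase (11.2 to 61.9 FPKM), and RAB31 (2.82 to 21.3 FPKM) were also among the 10 highest. The lowest included MYO6, a myosin motor (147 to 19.0 FPKM), the retinal reductase DHRS3 (116 to 15.4 FPKM), and the homeobox gene HOXB2 (8.96 to 0.422 FPKM) with the overlapping antisense HOXB-AS1 (10.4 to 0.841 FPKM), which cannot be told from each other without strand. Another kept gene overlapped 4 of the 10 highest and 5 of the 10 lowest.

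Averaged over both lines, limma called 11 genes higher and 11 lower with docetaxel at an adjusted p under 0.05, and 768 genes had an unadjusted p under 0.05. No gene was called by limma with the highest transcript only (452 unadjusted) or without the filter on low values (734 unadjusted). If no gene differed, a share of 0.05 of the genes tested would have an unadjusted p under 0.05. The 768 of 13472 genes lie close to that share, and the 452 of 12666 and 734 of 20506 lie below it, so these counts alone are no sign of an effect. Of the 22, 20 were listed at 0 in at least 1 library. The exceptions were CDKN1A, 4.41-fold higher and up in both lines (limma adjusted p = 0.0195), and USP41, a deubiquitinase gene with a close paralog (20.3, 1.06, 29.4 and 1.71 FPKM), 10.8-fold lower and down in both lines (adjusted p = 0.0100). The genes with the smallest limma p-values were listed at 0 in both untreated libraries, as PRR13 (0, 194, 0 and 171 FPKM), MIEN1 (0, 56.2, 0 and 50.9 FPKM, overlapping ERBB2), DDIT3 (0, 71.2, 0 and 40.9 FPKM, overlapping MARS) and FDX1L (overlapping CTD-2369P2.12), or in both docetaxel libraries. Those in both docetaxel libraries were SMARCC2 (54.5, 0, 28.6 and 0 FPKM, overlapping MYL6), SDR39U1 (overlapping KHNYN), AL139819.1 (overlapping SCD), RP13-1032I1.7 (overlapping HGS) and RFC4 (26.1, 0, 19.8 and 0 FPKM, overlapping EIF4A2). With limma restricted to the 12442 genes above 0 in all libraries, 68 were higher and 46 lower, and 927 had an unadjusted p under 0.05. There the prior degrees of freedom were infinite, so that genes whose lines went apart were called too, as ZNF888 was (0.138, 52.0, 36.9 and 48.1 FPKM).

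Among the lists, limma on all 13472 kept genes called 1 of 31 p53 targets higher with docetaxel over all genes and 6 adjusted over the list alone, which were CDKN1A, GADD45A, TP53I3, PLK3, BBC3 and C12orf5. Of 27 histone genes, limma called 0 over all genes, beside the 768 genes with an unadjusted p under 0.05, and 6 higher adjusted over the list alone, such as HIST1H2BG (14.3, 56.1, 2.88 and 12.2 FPKM) and HIST1H1C. Adjusted over the list alone, 4 tubulins were higher, of which TUBA1A and TUBA4A were each listed at 0 in 1 library and overlap another kept gene. Also higher were GREB1, CYP1B1 (7.31, 20.6, 4.68 and 22.2 FPKM), NEAT1 and the basal marker ACTA2, listed at 0 in 1 library. DDIT3 was the 1 call among stress response genes and RFC4 the 1 call among replication genes; both were also called adjusted over the list alone, as was CDC25C of the mitosis list, which was listed at 0 in both docetaxel libraries. In this fit none of the other lists had a limma call for docetaxel, over all genes (768 with an unadjusted p under 0.05) or adjusted over the list alone.

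The limma fit on genes above 0 in all libraries called more list members with docetaxel. It called 6 of 31 p53 targets higher over all genes and 13 adjusted over the list alone, and 4 of 24 histone genes and 12 adjusted over the list alone. Higher counts over all genes, then adjusted over the list alone, were 2 and 6 for interferon-stimulated genes, 0 and 4 for NF-kB genes, 2 and 3 for tubulins, and 1 and 5 for estrogen receptor targets. Immediate early genes had 1 and 4 higher and 1 lower in both forms. Counts of 1 and 2 higher were found for apoptosis regulators, stress response genes, drug transport and metabolism genes, and non-polyadenylated and nuclear RNAs, and 0 and 1 for blood cell markers. Lower counts were 1 and 4 for replication, 0 and 2 for mitosis, 0 and 1 for luminal identity and 0 and 1 for the endothelial marker. The remaining lists had no limma call in this fit, beside 927 genes with an unadjusted p under 0.05 over all genes.

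**Figure D1:**
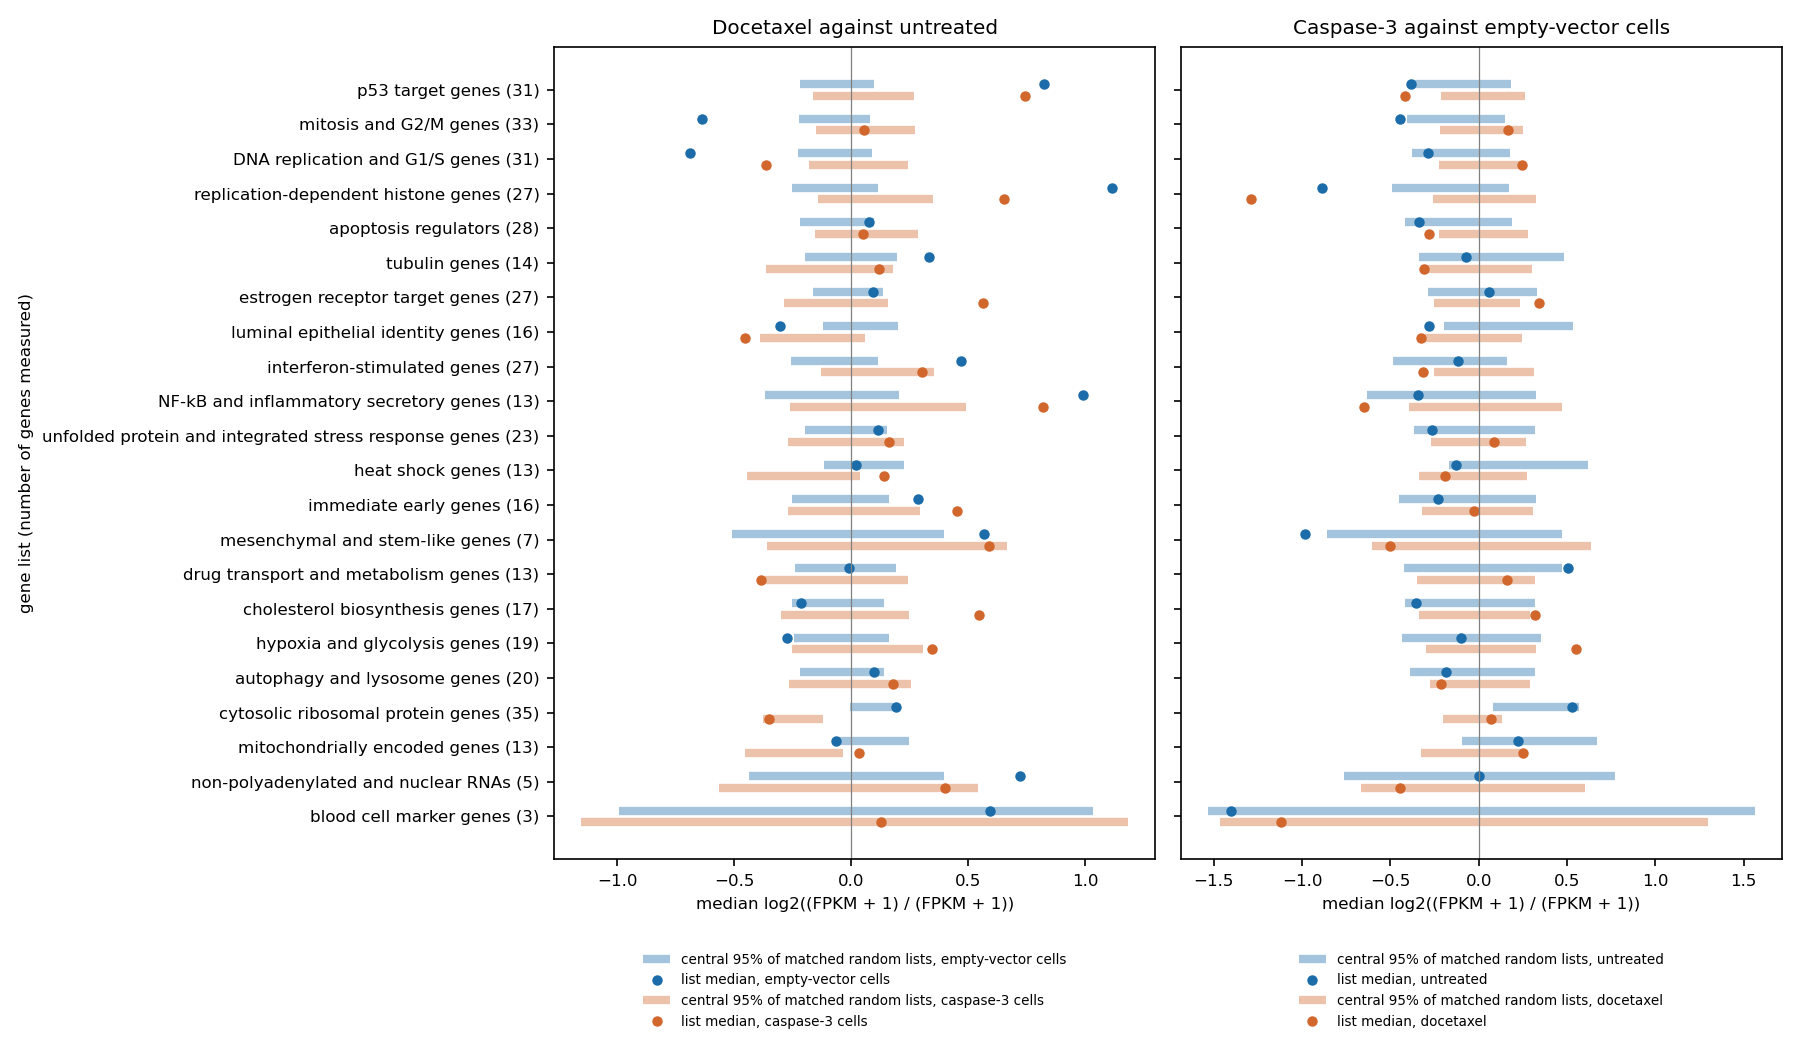
Median log2 ratio (horizontal axis) of each gene list (vertical axis, with the number of measured genes) for docetaxel against untreated in each line (left) and caspase-3 against empty-vector cells under each treatment (right); points are list medians and bars the central 95% of 10000 expression-matched random lists. The p53 medians of 0.82 and 0.74 lie right of their bars in both lines, while the mitosis medians are −0.64 in empty-vector and 0.05 in caspase-3 cells, the latter −0.03 under median-ratio scaling.

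Caspase-3 against empty-vector cells, untreated, asks how the lines differed before the drug. DHRS2 (ENSG00000100867, chromosome 14, positions 24099324 to 24114848), a mitochondrial short-chain reductase, had 12.5 FPKM in empty-vector and 1764 FPKM in caspase-3 cells (log2 7.03, 6.55 to 7.51), and IGFBP5, which binds insulin-like growth factors, had 1.69 and 166 FPKM (5.95, 5.65 to 6.26). The stress-induced regulator NUPR1 (3.67 and 172 FPKM), the antiviral tetherin BST2 (3.27 and 135 FPKM) and the serine protease PRSS23 (63.2 and 1009 FPKM) were also among the 10 highest. The 10 lowest included SERPINA3, an acute-phase protease inhibitor (150 and 7.93 FPKM; −4.08, −4.56 to −3.59), the lipocalin APOD (364 and 27.1 FPKM; −3.70, −4.05 to −3.35), BPIFB1 (52.9 and 0.241 FPKM), the lysosomal GALC (40.7 and 1.70 FPKM) and HLA-DQB1 (21.6 and 0.718 FPKM), which has close paralogs.

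By list, histone genes in untreated caspase-3 cells had 0 of 27 higher, 11 at least 2-fold lower, 13 within 2-fold and 3 listed at 0 (median −0.89, below the matched range). The 5 non-polyadenylated and nuclear RNAs had 0 higher, 2 at least 2-fold lower, 2 within 2-fold and 1 listed at 0. Their median of 0.00, within the matched range, was the ratio of the RNA listed at 0. It does not show that these RNAs were level. Mitosis and G2/M genes had a median of −0.45, with 2 of 33 lower and 31 within 2-fold; the cyclin CCNB2 had 44.2 and 21.4 FPKM. This median was inside the matched range with the highest transcript only and with status OK transcripts only. Luminal identity genes had a median of −0.28, with 1 of 16 higher, 2 lower and 13 within 2-fold: GATA3, a luminal transcription factor, had 525 and 238 FPKM, and SPDEF 96.0 and 262 FPKM. Its place below the matched range was lost with the same pair of settings. Mesenchymal and stem-like genes had a median of −0.98, with 0 of 7 higher, 2 lower, 3 within 2-fold and 2 listed at 0; it was −0.11, above the middle of the matched lists, among genes above 0 in all libraries, where SOX2 (22.1, 10.3, 0 and 0 FPKM) drops out. It was also inside the matched range at a pseudocount of 5 and with the highest transcript only. Drug transport and metabolism genes were the list above the matched range (0.50), with 4 of 13 higher, 1 lower and 8 within 2-fold. The steroid and carbonyl reductases AKR1C2 (65.5 and 866 FPKM) and AKR1C1 (12.3 and 135 FPKM), which are close paralogs, and the glutathione transferase GSTM3 (173 and 782 FPKM) were among them. That median was inside the matched range without the filter on low values, with the highest transcript only and among genes above 0 that overlap no other.

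For the other lists the untreated comparison was within the matched range, although members went both ways. Targets of p53 had a median of −0.38, with 2 of 31 higher, 4 lower and 25 within 2-fold: the p53 inhibitor MDM2 had 9.52 and 37.8 FPKM and the nuclease AEN 21.8 and 6.95 FPKM. Estrogen receptor targets had a median of 0.06 (−0.16 under sum scaling), with 4 of 27 higher, 5 lower, 17 within 2-fold and 1 listed at 0; the chemokine CXCL12 had 3.96 and 29.4 FPKM. Tubulins had a median of −0.07 (0.05 under median-ratio scaling), with TUBB3 at 304 and 63.1 FPKM. The others were replication (−0.29), apoptosis (−0.34), interferon (−0.12), NF-kB (−0.34), the unfolded protein and integrated stress response (−0.26), heat shock (−0.13, and 0.01 under median-ratio scaling), immediate early (−0.23), cholesterol (−0.35), hypoxia and glycolysis (−0.10), autophagy and lysosome (−0.19) and ribosomal proteins (0.53). The mitochondrial median was 0.23 and below 0 by less than 0.01 under sum scaling. In all, 1212 genes were at least 2-fold higher and 1552 lower in untreated caspase-3 cells, of which 326 and 338 were listed at 0 in a compared library, and 862 and 1184 genes passed among those above 0 in all libraries. The side with more genes depended on scaling: 43.8% of these genes were higher as deposited and 54.5% after median-ratio scaling.

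Caspase-3 against empty-vector cells after docetaxel asks how the treated lines differed. DHRS2 (8.83 and 1432 FPKM; log2 7.19, 6.78 to 7.60) and IGFBP5 (0.256 and 158 FPKM; 6.99, 6.69 to 7.29) were again the highest, followed by genes such as the collagen chaperone FKBP10 (3.19 and 66.3 FPKM) and LRG1 (0.780 and 26.7 FPKM). The lowest included UPK3A, a urothelial membrane protein (60.2 and 1.81 FPKM), APOD (478 and 27.8 FPKM), SERPINA3 (318 and 19.6 FPKM; −3.95, −4.30 to −3.60) and GFRA1, a receptor of glial-derived growth factor (50.1 and 3.34 FPKM). LOXL1 (24.1 and 0.973 FPKM) was also among the 10 lowest and overlaps its antisense gene. A total of 1091 genes were at least 2-fold higher and 1154 lower, of which 240 and 269 were listed at 0 in a compared library, and 801 and 819 passed among genes above 0 in all libraries.

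The estrogen receptor, glucose and sterol lists had medians above the matched range in this comparison, with most members within 2-fold. Estrogen receptor targets had a median of 0.34, above the matched range, with 8 of 27 at least 2-fold higher, 1 lower, 17 within 2-fold and 1 listed at 0; GREB1 had 16.9 and 105 FPKM (log2 2.57, 2.38 to 2.76) and the receptor kinase RET 9.81 and 56.6 FPKM. Hypoxia and glycolysis genes had a median of 0.55, with 5 of 19 higher and 14 within 2-fold; SLC2A1 had 24.8 and 121 FPKM (2.24, 2.03 to 2.45) and the prolyl hydroxylase P4HA1 6.76 and 21.3 FPKM. Cholesterol biosynthesis had a median of 0.32, with 3 of 17 higher, 1 lower and 13 within 2-fold, among them the epoxidase SQLE (43.9 and 100 FPKM). It was inside the matched range with the highest transcript only. Replication genes had a median of 0.25, with 30 of 31 within 2-fold and 1 listed at 0; it was inside the matched range under several settings, including either other pseudocount and no filter on low values.

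Histone, interferon and p53 genes had more members at least 2-fold lower than higher, and inflammatory genes went both ways. Of 27 histone genes, 15 were at least 2-fold lower, 0 higher, 11 within 2-fold and 1 listed at 0 (median −1.29), beside a median of −0.45 for non-polyadenylated and nuclear RNAs, within the matched range. Of 13 NF-kB and inflammatory secretory genes, 3 were lower, 3 higher and 7 within 2-fold (median −0.65): TNFAIP2 had 24.1 and 1.86 FPKM and amphiregulin AREG, whose reads are shared with the near-identical AREGB, 2.36 and 29.6 FPKM. Of 31 p53 targets, 5 were lower, 0 higher and 26 within 2-fold (median −0.42), with BBC3 at 39.2 and 15.9 FPKM and GADD45A at 52.1 and 22.0 FPKM. Interferon-stimulated genes had a median of −0.32, with 6 of 27 lower, 1 higher and 20 within 2-fold; IRF1, a transcription factor of the interferon response, had 33.9 and 5.26 FPKM, while BST2 was the higher gene. That median was inside the matched range at a pseudocount of 5, with the highest transcript only and among genes above 0 that overlap no other. Apoptosis regulators had a median of −0.28, with 2 of 28 higher, 6 lower and 20 within 2-fold; the pro-apoptotic BMF had 4.98 and 0.856 FPKM and BNIP3 13.6 and 35.6 FPKM, and the median was inside the matched range at a mean of at least 5 FPKM. Luminal identity genes had a median of −0.33, with 2 of 16 higher, 2 lower and 12 within 2-fold. It was inside the matched range with status OK transcripts only and among genes above 0 that overlap no other. Within the matched range were mitosis (0.17), tubulins (−0.31), the unfolded protein and integrated stress response (0.08), heat shock (−0.19), immediate early (−0.02), mesenchymal and stem-like (−0.50), drug transport and metabolism (0.16), autophagy and lysosome (−0.22), ribosomal (0.07) and mitochondrial genes (0.25).

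Averaged over both treatments, limma called 207 genes higher and 215 lower in caspase-3 than in empty-vector cells, and 2490 genes had an unadjusted p under 0.05. Both libraries of a line come from the same transfected line, so these calls cannot separate the cDNA from other differences between the lines. By limma 0 and 0 were called with the highest transcript only (1601 unadjusted) and 1 and 0 without the filter on low values (2462 unadjusted). Of the called genes, 109 were listed at 0 in at least 1 library. DHRS2 was 138-fold higher (limma adjusted p = 4.40e-05) and IGFBP5 88.7-fold higher (adjusted p = 0.000236), each under both treatments. By limma SERPINA3 was 16.2-fold lower (adjusted p = 0.000388) and APOD 14.7-fold lower (adjusted p = 0.000395), again under both. Also among the smallest p-values were genes listed at 0 in 1 line: PDAP1 (0, 0, 179 and 145 FPKM, overlapping ARPC1B), EMC9 (overlapping PSME1), FAM173A and P4HTM (overlapping WDR6). So were the neighbours PAGR1 (0, 0, 93.2 and 63.4 FPKM) and MVP (76.9, 90.3, 0 and 0 FPKM), whose spans overlap and whose values mirror each other. With limma on the genes above 0 in all libraries, 572 were higher and 697 lower, and 2719 had an unadjusted p under 0.05.

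Among the lists, limma on all 13472 kept genes called 0 of 27 histone genes higher and 5 lower over all genes, and 0 and 16 adjusted over the list alone; HIST1H2BG was 4.12-fold lower (limma adjusted p = 0.0134). Estrogen receptor targets had 4 higher and 1 lower, and 7 and 3 adjusted over the list alone: CXCL12 was 5.56-fold higher (limma adjusted p = 0.00654), GREB1 4.73-fold higher (adjusted p = 0.00949), and ADORA1 and RET were also higher, while AGR3, listed at 0 in both caspase-3 libraries, was lower (5.59, 8.43, 0 and 0 FPKM). Drug transport and metabolism genes had 4 higher and 0 lower, and 5 and 2 adjusted over the list alone, with AKR1C2 9.17-fold higher (limma adjusted p = 0.00243). Hypoxia and glycolysis genes had 2 higher, SLC2A1 and NDRG1, and 4 adjusted over the list alone. NF-kB genes had AREG higher and TNFAIP2 lower, and 4 and 4 adjusted over the list alone. Among the higher was TGFB1, listed at 0 in 1 library (0, 14.6, 35.2 and 23.2 FPKM). Interferon genes had BST2 higher and IRF1 lower, and 1 and 6 adjusted over the list alone. Among the lower was IRF9, listed at 0 in 1 library (22.8, 27.4, 0 and 18.7 FPKM).

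The remaining limma calls for caspase-3 were few. Luminal genes had SPDEF higher and TFAP2A lower (2 and 2 adjusted over the list alone), mesenchymal genes had ALDH1A3 (overlapping RP11-66B24.2) and SOX2, listed at 0 in both caspase-3 libraries, lower (0 and 3), and tubulins had TUBB3 lower (1 and 3). Stress response genes had PSAT1 higher (3 and 1), which was listed at 0 in 1 library (0, 0.155, 7.78 and 6.89 FPKM). AEN of the p53 list, KLF6 of the immediate early list and LSS of the cholesterol list were each lower over all genes and adjusted over the list alone. Adjusted over the list alone, COL5A1 of the fibroblast list and HBA1 and ITGAM of the blood list, ITGAM listed at 0 in 1 library, were lower and MYLK of the basal list higher. None of the mitosis, replication, apoptosis, heat shock, autophagy, ribosomal, mitochondrial, non-polyadenylated or endothelial lists had a limma call in either form in this fit, beside 2490 genes with an unadjusted p under 0.05 over all genes.

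The limma fit on genes above 0 in all libraries called more list members here too. Its prior degrees of freedom were infinite, so a gene's own disagreement between treatments did not count against a call. The larger counts are therefore no stronger evidence. Over all genes it called 14 of 24 histone genes lower and 0 higher (19 and 0 adjusted over the list alone), 4 of 31 p53 targets lower and 0 higher (4 and 0), and 7 of 26 estrogen receptor targets higher and 2 lower (7 and 2). In the order higher and lower over all genes, then adjusted over the list alone, it gave 2 and 6, 3 and 6 for interferon genes, 2 and 4, 3 and 4 for NF-kB genes, 1 and 4, 1 and 5 for apoptosis regulators, and 0 and 3, 2 and 4 for mitosis. It gave 4 and 2, 5 and 2 for drug transport and metabolism, and 4 and 0, 5 and 0 for hypoxia and glycolysis. It gave 3 and 1, 4 and 1 for stress response genes, 2 and 3, 2 and 4 for luminal identity, and 1 and 2, 1 and 3 for autophagy and lysosome. Smaller counts were 0 and 2 in both forms for tubulins and for mesenchymal genes, 0 and 1 in both for cholesterol and fibroblast genes, and 1 and 0 in both for heat shock, ribosomal and basal genes. Immediate early genes had 0 and 1, 1 and 1, non-polyadenylated and nuclear RNAs 0 and 1, 1 and 3, and blood markers 0 and 0, 0 and 1. Replication, mitochondrial and endothelial genes had no limma call, beside 2719 genes with an unadjusted p under 0.05 over all genes.

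**Figure D2:**
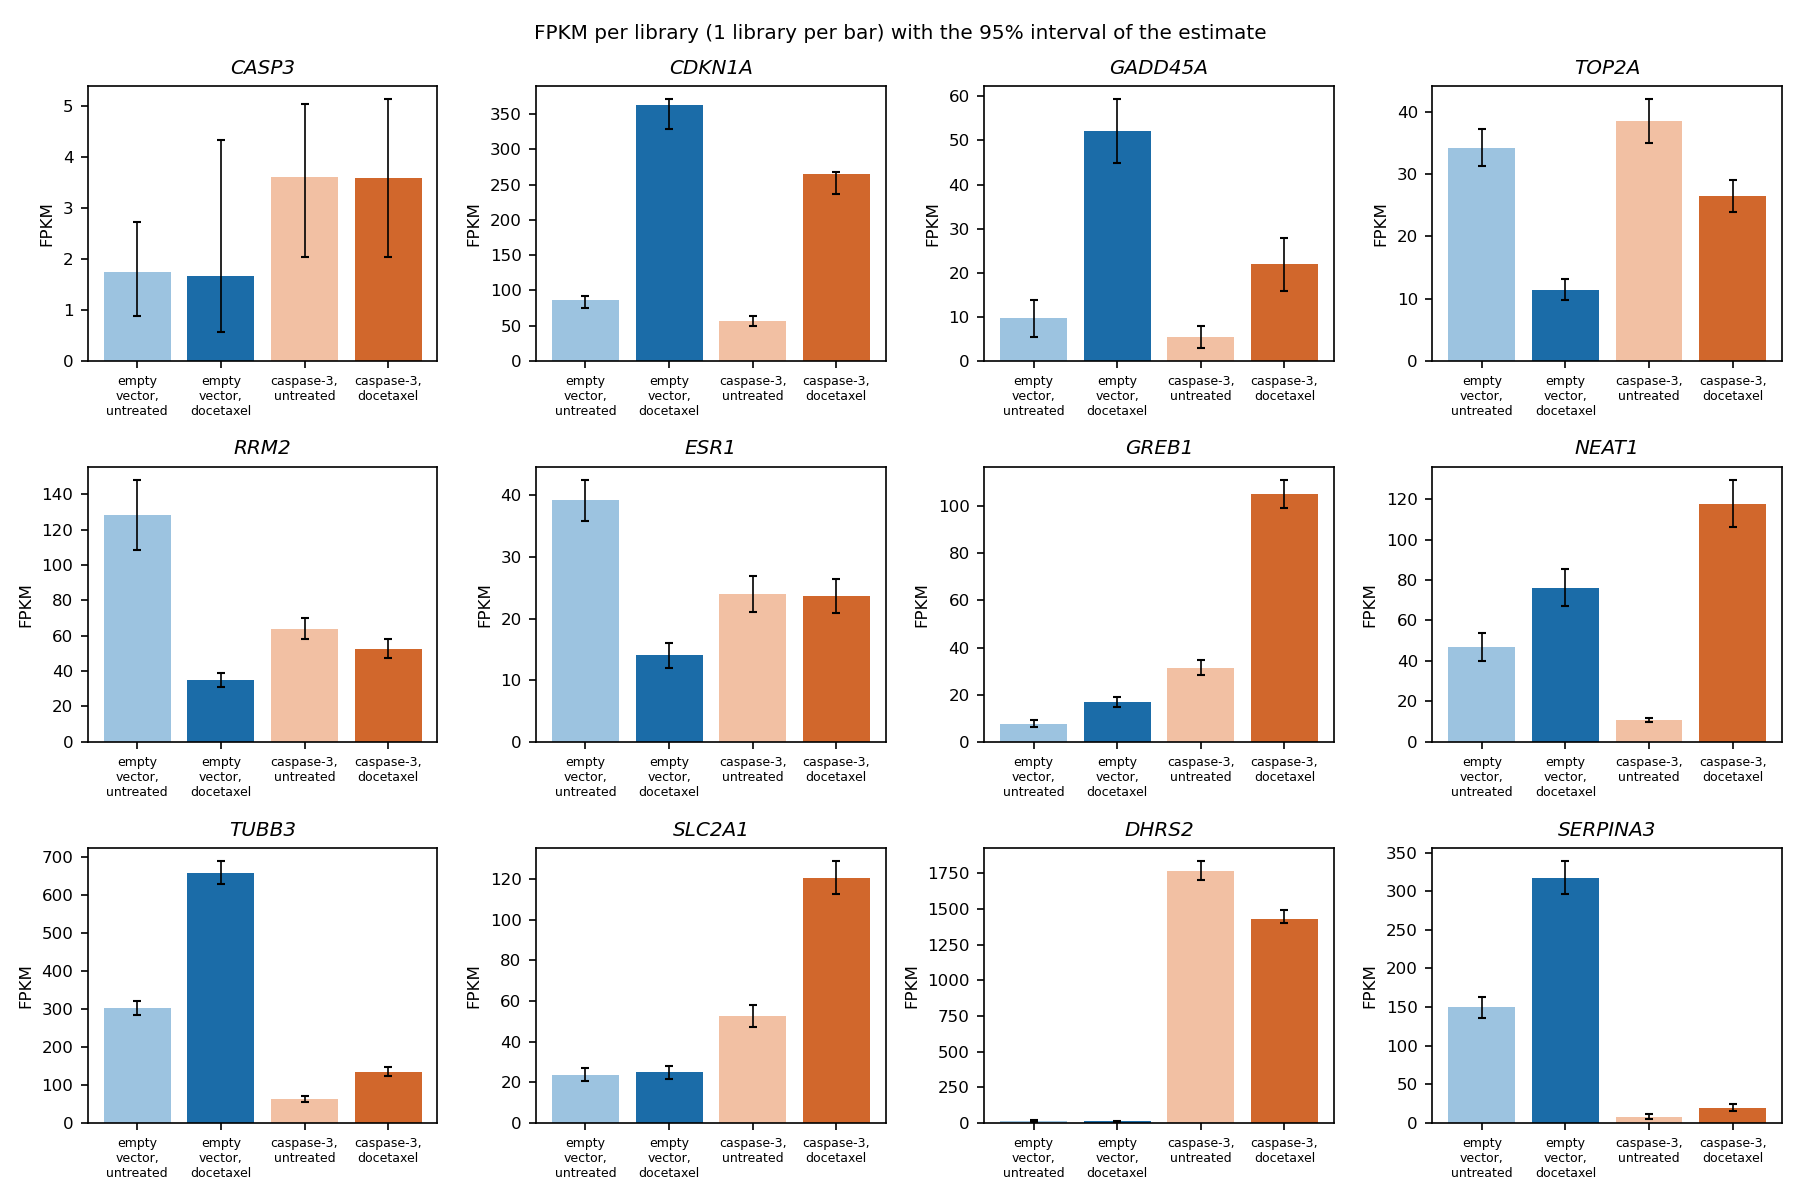
FPKM (vertical axis, linear from 0) of 12 genes in the 4 libraries (horizontal axis); each bar is 1 library and each line the 95% interval of the estimate. CDKN1A stands at 363 and 265 FPKM after docetaxel against 86.5 and 55.9 untreated, and DHRS2 at 1764 and 1432 FPKM in caspase-3 against 12.5 and 8.83 in empty-vector cells.

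The difference of the 2 docetaxel responses asks where caspase-3 cells answered the drug unlike empty-vector cells; it has no test of its own here. For mitosis and G2/M genes the response of caspase-3 cells was above that of empty-vector cells by a median log2 of 0.60 (middle of matched lists 0.14). Of 33, 4 were at least 2-fold above, 0 below, 27 within 2-fold and 2 listed at 0, beside 1491 of all 13472 genes at least 2-fold above. Relative to matched lists, interferon (−0.60), hypoxia and glycolysis (0.60) and cholesterol genes (0.55), among others, lay further out than mitosis (0.46). NUSAP1, which bundles spindle microtubules, had 27.2, 10.4, 30.4 and 24.9 FPKM, and the checkpoint kinase BUB1 16.2, 8.62, 8.56 and 10.9 FPKM. Hypoxia and glycolysis genes (median 0.65, with 5 of 19 above, 0 below, 13 within and 1 listed at 0) and cholesterol biosynthesis genes (0.58, with 5 of 17 above, 0 below and 12 within) differed the same way. SLC2A1 had 23.8, 24.8, 52.5 and 121 FPKM and SQLE had 58.9, 43.9, 56.0 and 100 FPKM. Estrogen receptor targets (0.33, with 3 of 27 above, 0 below, 23 within and 1 listed at 0) were above too, with IRS1 at 26.5, 21.4, 8.63 and 21.9 FPKM. ESR1 itself had 39.2, 14.0, 24.0 and 23.6 FPKM (difference 1.40, 1.07 to 1.72). The cholesterol and estrogen medians were inside the matched range with the highest transcript only.

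Interferon-stimulated genes lay on the other side, with a median difference of −0.42, 8 of 27 below, 0 above, 18 within 2-fold and 1 listed at 0; IFI6 had 13.6, 50.6, 57.5 and 58.7 FPKM. Ribosomal protein genes had a median of −0.54, with 1 of 35 above and 34 within 2-fold. It lay just below the matched range of −0.53 to −0.21 (middle −0.35), and inside that range with the highest transcript only. The histone median was −0.17, below the matched range, and 0.00 under sum scaling, with 1 of 27 above, 9 below, 14 within 2-fold and 3 listed at 0; it was inside the matched range under median-ratio scaling, at a mean of at least 5 FPKM and with the highest transcript only. All 13 heat shock and all 13 mitochondrial genes were within 2-fold, with medians of 0.21 and 0.19 above their matched ranges. The middles of those matched lists were −0.28 and −0.36, so much of the distance lay in the matched genes. Over the 11 settings the mitochondrial median was as low as −0.03. Medians within the matched range were p53 targets (−0.11, and 0.11 under sum scaling), replication (0.35), apoptosis (−0.09, and 0.13 under sum scaling), tubulins (−0.08, and 0.16 under sum scaling), luminal identity (−0.04, and 0.20 under sum scaling), NF-kB (−0.12, and 0.10 under sum scaling), the unfolded protein and integrated stress response (0.21), immediate early (0.13, and −0.04 under median-ratio scaling), mesenchymal and stem-like (0.37), drug transport and metabolism (−0.40), autophagy and lysosome (0.01, and −0.16 under median-ratio scaling) and non-polyadenylated and nuclear RNAs (−0.32).

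Single genes with the largest differences included IDS (54.7, 17.5, 11.2 and 61.9 FPKM; 3.95, 3.58 to 4.31), COPZ2 (5.50, 4.31, 10.9 and 108 FPKM) and LRFN5 (11.0, 0.0874, 2.93 and 3.38 FPKM) above, and ZNF888, GUSBP2 (0.854, 1.04, 29.2 and 0.826 FPKM) and C14orf119 below (14.3, 98.2, 81.6 and 17.4 FPKM; −4.87, −5.30 to −4.43). C14orf119 overlaps ACIN1, HERC3 and GGT3P of the 5 highest also overlap other kept genes, and GUSBP2 is a pseudogene with close copies. A total of 1491 genes were at least 2-fold above and 1109 below, of which 330 and 354 were listed at 0 in a library; 1161 and 755 passed among genes above 0 in all libraries. The side with more genes depended on scaling, with 57.3% above as deposited and 44.0% after median-ratio scaling. The median over all kept genes was 0.13 for the difference and 0.35 under sum scaling; in the 4 comparisons, in the order above, it was −0.06, 0.06, −0.12 and 0.02 as deposited and −0.12, 0.22, −0.33 and 0.03 under sum scaling.

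The responses shared some genes. Among the 12442 genes above 0 in all libraries, 63 were at least 2-fold higher with docetaxel in both lines, where independence would give 15.6, and 30 were lower in both, where it would give 12.1. CDKN1A, GADD45A, GREB1, TUBB3, LIF and CYP1B1 were among those higher in both and HOXB2 among those lower in both. Another 23 were higher in empty-vector and lower in caspase-3 cells, and 21 the reverse, against 12.4 and 15.2 if the responses were independent. Across all 13472 genes, which are not independent replicates, Pearson's r of the responses was 0.045 (bootstrap 95% interval −0.000 to 0.087) and Spearman's rho 0.022.

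**Figure D3:**
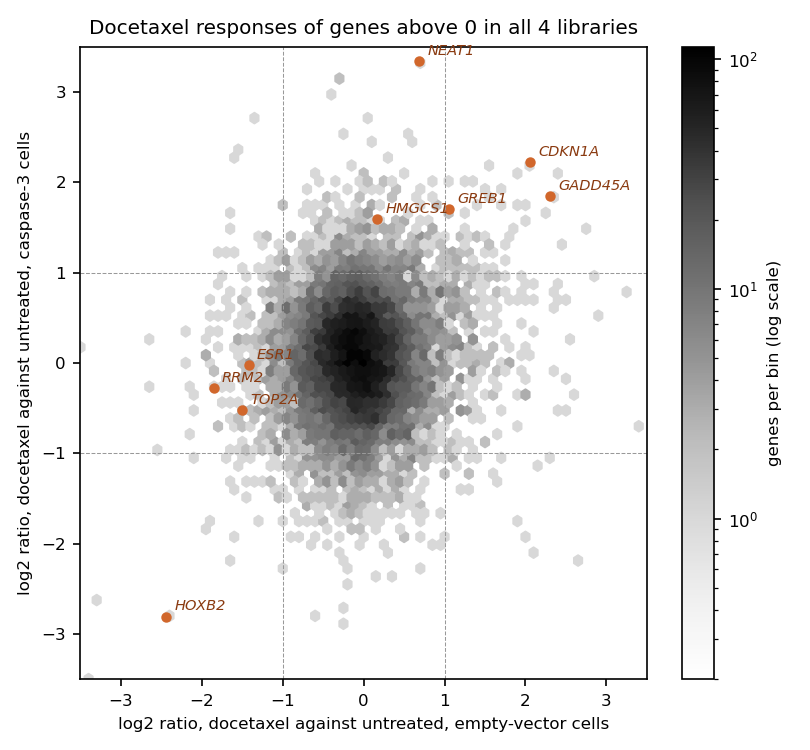
Log2 ratio of docetaxel against untreated in empty-vector cells (horizontal axis) and caspase-3 cells (vertical axis) for the 12442 genes above 0 in all 4 libraries, as hexagonal bins shaded by the number of genes on a log scale; 3 genes lie outside the axes and dashed lines mark 2-fold. CDKN1A lies at 2.06 and 2.23 and GADD45A at 2.31 and 1.85, RRM2 at −1.86 and −0.27, and the cloud as a whole shows little slope (r 0.045 over all kept genes).

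Few markers of other cell types passed the filters. Of the fibroblast markers, 2 of 12 were measured: COL1A1 (2.54, 2.12, 2.05 and 5.83 FPKM) and COL5A1 (4.99, 4.62, 0.313 and 0.413 FPKM). The endothelial list had 1 of 8, CDH5 (1.51, 0.314, 3.11 and 0.420 FPKM), and the basal mammary list 2 of 10, ACTA2 (1.34, 8.31, 0 and 4.59 FPKM) and MYLK (0.0968, 0.146, 2.45 and 7.74 FPKM, overlapping its antisense gene). Blood cell markers had 3 of 12, with medians of 0.59, 0.13, −1.40, −1.12 and −0.47 in the 4 comparisons and the difference, all within the matched range. By contrast, the luminal keratin KRT18 had 2011, 1427, 1784 and 1130 FPKM.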

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

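The tests of a chance count of 0, of the spread between the lines and of lower levels in untreated caspase-3 cells were chosen only after the result was seen. Apart from the range of matched sets, the intervals in this section are bootstraps over genes, which are not independent replicates.

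In 3 lists the docetaxel medians of the lines had opposite signs, both as ratios and relative to matched lists, with at least 1 of them and their difference outside the matched range; the difference was not tested. Hypoxia and glycolysis genes had a difference of 0.65 (−0.27 in empty-vector and 0.34 in caspase-3 cells). Cholesterol biosynthesis genes had a difference of 0.58 (−0.21 and 0.55). Mitochondrially encoded genes had a difference of 0.19 (−0.06 and 0.04), and the 2 medians change sign under median-ratio scaling. Over the 11 settings their difference was as low as −0.03. Mitosis (−0.64 and 0.05, or −0.03 under median-ratio scaling) and ribosomal protein genes (0.19 and −0.35) also had ratios of opposite sign, but the former not relative to matched lists, and the latter with both medians within the matched range. Transcripts under 300 nt, which entered the comparisons only where they belong to a kept gene, carried 35.0%, 25.6%, 18.3% and 35.9% of the summed FPKM in the 4 libraries. AC138123.2, a transcript of 78 nt, was listed at 126432, 51054, 12975 and 141215 FPKM.

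One pattern was that 62 genes were listed at 0 in 1 library and at 10 FPKM or more in the other 3. A chance count of 0 at this depth is argued against, since a median of 134 fragments was expected in the library listing 0 (interval 98.5 to 165, lowest gene 26.6). The rule of 10 FPKM or more in the other 3 makes such counts high by construction. An estimate lost at loci where genes overlap stays open as a candidate explanation: 72.6% of these genes overlapped another kept gene, against a middle of 25.8% (14.5% to 35.5%) in matched sets. Whether the reads went to the overlapping gene cannot be told apart from other losses, because the share of the gene's read bases found again on overlapping genes had a median of 0.560 with an interval of 0.00510 to 0.851. No biological explanation was tested.

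Another pattern was that the docetaxel ratios of the lines hardly correlated across genes. Among 2297 genes with a mean of at least 50 FPKM, r was 0.0445 (−0.191 to 0.268). That set kept genes listed at 0, such as PRR13, whose large ratios can outweigh the others in r. The test therefore cannot decide on counting noise of low genes, which stays open. A trend with transcript length and GC content as the whole cause is argued against by its size. Its SD was 0.0970 in empty-vector and 0.215 in caspase-3 cells, against 0.501 and 0.577 for the responses of genes above 0 in all libraries. With genes listed at 0 kept, r was 0.0814 (0.0334 to 0.128) once the trend was removed and 0.0456 before. For a difference confined to the untreated caspase-3 library, the spread between the docetaxel libraries was 0.892 (0.868 to 0.916) times that between the untreated ones. The value would be 0.746 if that library, apart from the line difference, made the whole response and the empty-vector response widened both spreads alike. It would be higher if the empty-vector response lay in its docetaxel library alone, so this test cannot decide. That library as the whole or a part of the cause, a different response of the lines and a difference between single cultures stay open, because each group has 1 library.

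A further pattern was in the docetaxel medians of mitosis genes, −0.64 in empty-vector and 0.05 in caspase-3 cells (−0.03 under median-ratio scaling), and replication genes, −0.69 and −0.36, although the difference for replication was within the matched range. For both lists together and relative to matched genes, the median difference of responses was 0.26 (0.15 to 0.48) before and 0.16 (0.06 to 0.34) after a length and GC trend was removed; the interval spans 0.13, the level at which the trend would account for as much as it left, so the trend cannot be told apart. The difference of responses is also the line difference after docetaxel minus the line difference when untreated. Lower levels in untreated caspase-3 than in untreated empty-vector cells thus restate a part of the pattern and are no independent test of a cause. Relative to matched genes, the median of the lists was −0.23 (−0.37 to −0.04) in the untreated comparison. After docetaxel it was 0.17 (0.05 to 0.32). These intervals resample list genes, which vary together, and do not cover the spread between cultures. A different response of the lines stays open, untested.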

How the results depend on the processing

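The alternatives chosen only after the result was seen were genes above 0 in all libraries, such genes that overlap no other kept gene, and non-overlapping intervals in genes above 0 in both libraries. No paired analysis of replicates was possible because each group had 1 library. The averaged limma comparisons do set libraries against each other within line or within treatment. Counts that answer a comparison stayed within 1.5 times their value in 94 cases and moved further in 80. Of the values of single genes and lists, 6307 held, 484 moved and 26 changed direction. For a list, direction means the side of the middle of its matched lists, so a change of sign under scaling alone is not counted. Of the 49 list medians outside the matched range, 26 kept their side under all 11 settings, among them p53 targets with docetaxel in both lines, mitosis and replication in empty-vector cells, and histones in both comparisons of the lines. Pearson's r of the responses ran from 0.014 (highest transcript only) to 0.085 (above 0 and overlapping no other gene). The CASP3 ratio ran from 0.36 (pseudocount 5) to 1.02 (pseudocount 0.1) when untreated and from 0.37 to 1.07 after docetaxel, with no value at a mean of at least 5 FPKM, where the gene drops out. Lists with fewer than 3 measured genes have no median.

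With a pseudocount of 0.1, 899 genes were lower with docetaxel in empty-vector cells and 1383 higher in caspase-3 cells; limma gave 5 higher and 7 lower for docetaxel, and 110 and 103 for caspase-3. With a pseudocount of 5, which shrinks ratios of low genes by construction, higher and lower genes were 206 and 154 (docetaxel, empty-vector), 193 and 332 (docetaxel, caspase-3), 634 and 518 (lines, untreated), 425 and 509 (lines, docetaxel) and 456 and 562 (difference of responses). Without a filter on low values, 907 genes were higher with docetaxel in empty-vector cells, and limma called 0 and 0 for docetaxel (734 at an unadjusted p under 0.05) and 1 and 0 for caspase-3 (2462 unadjusted). At a mean of at least 5 FPKM, where fewer genes were tested, the counts in the same order were 251 and 226, 340 and 380, 735 and 842, 567 and 619, and 702 and 612. With sum scaling, 2417 genes were lower in untreated caspase-3 cells, 2390 were above in the difference, and limma called 346 lower for caspase-3. With all gene lengths limma called 57 and 41 for caspase-3, and without a trend 6 and 7 for docetaxel and 78 and 77 for caspase-3.

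With each gene's highest transcript only, 908 and 869 genes were higher and lower with docetaxel in empty-vector cells and 1319 higher in caspase-3 cells, and limma called 0 and 0 for docetaxel (452 unadjusted) and 0 and 0 for caspase-3 (1601 unadjusted); the cause was not tested. Among genes above 0 in all libraries, where fewer genes were tested, docetaxel gave 347 and 337 in empty-vector cells and 446 lower in caspase-3 cells, and limma called 68 and 46 for docetaxel and 572 and 697 for caspase-3. Among those that overlap no other gene the counts were 271 and 262, 417 and 332, 649 and 927, 617 and 656, and 876 and 574, with 59 and 40 and 465 and 588 by limma. With non-overlapping intervals, docetaxel gave 353 and 324 in empty-vector cells and 498 and 449 in caspase-3 cells. With these intervals in genes above 0, the counts for the 4 comparisons were 226 and 207, 351 and 296, 665 and 1009, and 643 and 688.

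Direction, taken for lists relative to their matched lists, changed for few values, and the cause was not tested. The list medians given above that changed sign under median-ratio or sum scaling are not counted here. The mesenchymal median in the untreated comparison was −0.11 at a mean of at least 5 FPKM, −0.11 among genes above 0 and −0.0234 among those that overlap no other, each above the middle of its matched lists. With the highest transcript only, docetaxel gave 0.45 for BNIP3L and 0.0730 for RPL22 in empty-vector cells, and 1.84 for PCCA, −2.86 for HMGCS1 and −0.37 for FDPS in caspase-3 cells. The lines differed by −0.47 for TUBB6 and −0.14 for NDRG1 when untreated, and by 2.20 for RELB, −0.27 for FDPS and −0.49 for COL1A1 after docetaxel. The difference of responses was −0.0209 for RRM2, −1.64 for POLA1, −0.41 for CYCS, 0.17 for TUBB6, 3.18 for RELB, −2.53 for HMGCS1, −0.0097 for FDPS, −0.0552 for BNIP3L and −0.11 for RPL22. With status OK transcripts only, docetaxel in empty-vector cells gave −0.43 for RP11-43F13.1 and −0.0217 for AC012318.3, and CYFIP2 gave −1.37 in the untreated comparison and 1.24 in the difference. Depth limits low genes: the deposited intervals had a median half-width of 60.5% to 64.8% of the value at 1 to 2 FPKM and of 12.6% to 15.1% at 50 to 100 FPKM.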

Other observations

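Some named members of the lists, not described above, had the following values, which carry no test of a theme. XBP1, a transcription factor of the secretory pathway, had 373, 386, 741 and 891 FPKM, and TRIB3, a pseudokinase of the integrated stress response, 24.8, 19.8, 56.6 and 42.8 FPKM. DDIT4, an inhibitor of mTOR signalling, had 33.8, 56.9, 16.1 and 43.7 FPKM. Among regulators of apoptosis, BCL2L11, which encodes BIM, had 9.04, 14.1, 3.40 and 6.35 FPKM, and MCL1, an inhibitor of apoptosis, 85.2, 73.6, 40.1 and 51.5 FPKM. The ribosomal gene RPS25 had 957, 1093, 2345 and 2211 FPKM and TUBB2B, a neuronal beta-tubulin, 8.22, 37.0, 10.0 and 10.4 FPKM.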
